A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

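Wild-type BY4741 yeast was grown in rich medium at 30 °C to an A600 of 0.8, and poly(A)+ RNA was purified from total RNA, per the labels' protocols. The RNA was treated with 5 units of TAP, or left without the enzyme in a parallel reaction, ligated to a 5′ adapter, fragmented and ligated to a 3′ adapter. It was then reverse transcribed and amplified by 10 cycles of PCR, and products of about 250 bp were selected and amplified by 8 more cycles. The 6 libraries were 3 with TAP and 3 without. The labels do not say whether the libraries of a group came from separate cultures.

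Reads were mapped with BWA 0.6.2 and handled with SAMtools 0.1.18 against the sacCer3 build, per the submitters' processing notes. The authors deposited 2 tables of genomic positions, which per the file headers give a chromosome, a coordinate and an ORF name for each site, and for the TSS table also a 0 or 1 in each of a pair of columns named internal and flag. The meaning of the flag column, how 1 site per ORF was chosen, how reads of different libraries were combined and what read support was required are not given in the sources used here. A site that needs many reads would be missing more often in weakly transcribed genes, and a search limited to a distance from the coding sequence would cap the UTR lengths. Whether fragmentation and size selection affected all genes alike was not tested. A tail read at a genomic A cannot be placed to the base, since a templated A and a tail A look alike.

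Names were matched to the RefSeq annotation of build R64, which has the same sequence coordinates as sacCer3: all matched positions lay on the chromosome of their gene. Of 5207 TSSs and 5277 PASs, 3 and 4 carried names that the annotation of nuclear protein-coding genes does not hold and were left out. Coordinates are 1-based. The 5′ UTR length is the number of bases between the TSS and the first base of the annotated coding sequence, and the 3′ UTR length the number of bases from the stop codon to the PAS. Both are genomic lengths with introns not removed, and lengths of 1 base or more entered the medians. The annotation holds no introns in 5′ UTRs. Genes with near-identical copies are reported as uncertain.

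The tests of the report, the gene lists, the sites and the rule for named genes were fixed before the data were examined, and each part of the closing section says which of its tests were chosen later. UTR lengths of each list were compared with those of all other genes by a two-sided permutation test of the mean rank with 100000 permutations. Lists of fewer than 10 measured genes were described and not tested. Shares of genes with a mapped end, a TATA element, an upstream ATG or a regulatory site were compared by two-sided Fisher's exact tests. TATA, initiator and poly(A) elements were compared with control windows of the same genes by exact McNemar tests. Upstream ATGs were compared with 1000 shuffles of the bases within each 5′ UTR. P-values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Medians carry 95% bootstrap intervals over genes from 1000 resamples, and shares carry 95% Wilson intervals. All of these cover the choice of genes and not the error between libraries, and the depth per library is unknown. Where an exact p fell below the smallest number that can be represented, its -log10 was computed from log probabilities.

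The 19 gene lists were cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, glycolysis and fermentation, chaperones, histones, transcription factors, cell cycle control, the nuclear-encoded respiratory chain, cell wall proteins, the proteasome, amino acid biosynthesis, ergosterol synthesis, genes with described upstream ORFs, galactose and alternative carbon genes, meiosis, genes specific to either mating type, and the marker genes deleted in the strain. All their names were found in the annotation. The named genes were the 12 longest and 6 shortest UTRs at each end, leaving out UTRs that cover another coding sequence on the same strand. They also included the longest, the shortest and the 2 nearest the median of each list past the threshold, and all members of the upstream ORF, histone, mating-type and marker lists, of which a single gene is not reported here. The 8 convergent pairs with the longest overlap, the 6 divergent pairs with the nearest TSSs and the 8 genes with most upstream ATGs completed the rule.

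The comparison of libraries with and without TAP was foreseen as a count test and was not run, since the tables hold positions only. Alternatives changed the genes kept, the statistic permuted, the motif, the window, the strand, the control or the background. The rank test was tested on simulated data in which lists of 60 among 4946 genes had lengths changed 2.0-fold, and called 20 of 20, with 10 of 20 called at 1.5-fold, 1 of 20 at 1.25-fold and 0 of 20 with no change. For lists of 15 genes it called 17 of 20 at 2.0-fold and 4 of 20 at 1.5-fold. All 20 lists of a run were lengthened together, so changed genes also lay in the comparison group of each list. Shortening was not simulated, so these rates do not give the power for a few changed groups among unchanged genes. The TATA search found 21.9% in 2000 simulated windows with 20.5% planted. The simulated windows held all bases in equal shares, and windows without planting had the element in 2.3%. The real control windows had it in 8.38%, so the simulation does not give the rate of chance matches in promoters. The annotated coding sequences opened with ATG in 6004 of 6008 genes. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.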

Results

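Both ends of polyadenylated transcripts were mapped in BY4741, a MATa laboratory strain of Saccharomyces cerevisiae that carries deletions at HIS3, LEU2, MET17 and URA3. The cells grew in rich glucose medium at 30 °C to an A600 of 0.8. The assay, SMORE-seq, ligates an adapter to the 5′ end of the RNA after tobacco acid pyrophosphatase (TAP) has removed the cap, so that capped ends can be read at single-base resolution. Of the 6 libraries, 3 were made with TAP and 3 without it. The values analysed are 2 tables of positions, a transcription start site (TSS) or a polyadenylation site (PAS) for each gene, with 1 site per gene. The tables give no read counts and no values per library, so the depth is unknown, replicates cannot be compared, and the libraries with and without TAP could not be set against each other. Errors are therefore spreads over genes, and genes are not independent replicates.

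Of 6008 annotated nuclear protein-coding genes, 4971 had both ends, 233 a TSS only, 302 a PAS only and 502 neither. The matched tables hold 5204 TSSs and 5273 PASs. The 5′ untranslated region (UTR) had a median of 53 bases (95% bootstrap interval over genes 52 to 55, n = 4946), with quartiles at 30 and 104. The 3′ UTR had a median of 120 bases (118 to 123, n = 5271), with quartiles at 84 and 173. A 5′ UTR of 10 bases or fewer was found in 258 genes and one of over 300 bases in 186. The TSS fell on the first base of the start codon in 49 further genes and past it in 209, and these were left out of the 5′ UTR lengths. The PAS fell on the last base of the stop codon in 2 genes.

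The longest 5′ UTR, 2335 bases, belonged to FLO5, a flocculin gene on chromosome VIII (coding sequence 525392 to 528619, TSS at 523057). SET4 followed with 1322 bases and THI72 with 1082, and no other gene went above 1000. ULI1 had 984 bases, RRT13 927 and PDR18 913. The gene for the 14-3-3 protein BMH2 had 889. YLL067C (924 bases) and YLL066C (916 bases) are near-identical copies close to a telomere, and FLO5 has close paralogs, so positions assigned to these genes are uncertain. The shortest 5′ UTRs of 1 base were found in BOL1, SUS1, FUB1, SNU23, MSC2 and IPK1, among others. At the 3′ end the lengths stopped at 385 bases, the value of HAC1, the transcription factor gene of the unfolded protein response. That value is counted from the end of an annotated coding sequence of 2 exons, and whether the HAC1 transcripts mapped here were spliced was not measured. CEP3 and BRE5 had 382 bases, NAM7 381 and MSS11 380, and 57 genes lay above 350 bases. Whether the authors limited the distance searched is not given in the sources used here, and a limit near 385 bases would make the longest 3′ UTRs, and the medians of groups with many of them, too short. The shortest 3′ UTRs were those of SPC98 with 1 base, GRS2 with 2, FKS3 with 4 and SCS22 with 6, and MAK5, NTG1 and GAT1 were among those with 7.

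**Figure D1:**
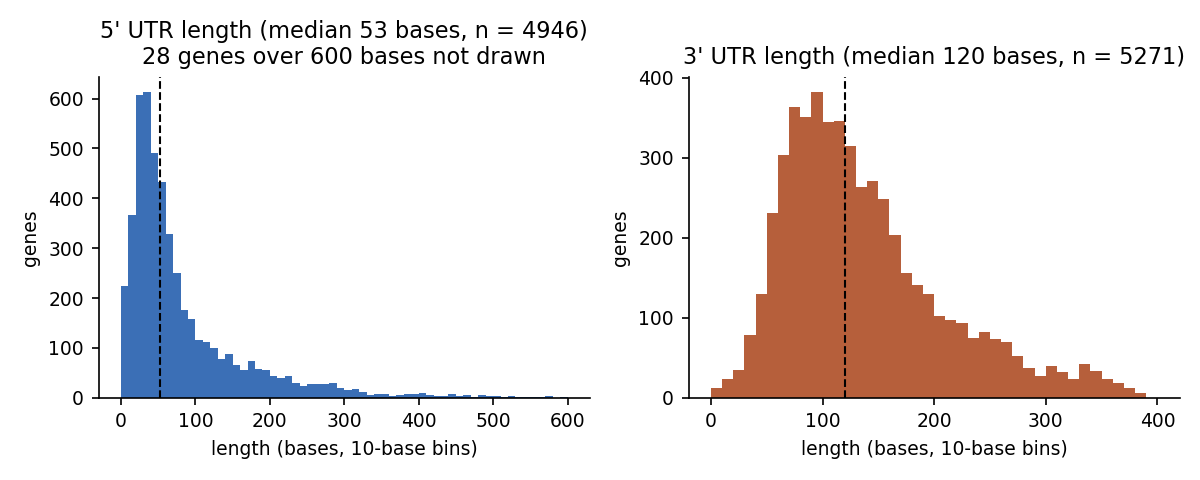
Histograms of the 5′ UTR length (left) and 3′ UTR length (right) in bases, in 10-base bins, with the number of genes on the vertical axis. Dashed lines mark the medians of 53 and 120 bases, and the 3′ lengths end at 385.

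Gene groups were compared first for the length of the 5′ UTR. Cytosolic ribosomal protein genes had short 5′ UTRs, with a median of 31.5 bases (95% bootstrap interval 27 to 37, n = 132) against 54 in all other genes. RPL13B had 4 bases, RPL31A 31 and RPL4B 32. RPS22B was the longest with 611, a genomic length that includes the intron known in its leader. Mitochondrial ribosomal protein genes were shorter too, with a median of 44 bases (36 to 51, n = 61), from 3 in RSM22 to 142 in MRPL7. Ribosome biogenesis genes had a median of 43 bases (35 to 45, n = 59), with BRX1 at 8, NOP2 at 43, DBP3 at 44 and NOP1, the gene for fibrillarin, at 143. Sequence-specific transcription factor genes had long 5′ UTRs, with a median of 111 bases (92 to 149, n = 75) against 53. SFP1 had 637 bases, FKH1 111, CRZ1 109 and DAL82 3. Cyclin and cell cycle control genes had a median of 100 bases (78 to 140, n = 27), from 42 in the phosphatase gene MIH1 to 349 in the B-type cyclin gene CLB2.

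Genes described as carrying upstream ORFs, a group chosen for a feature that needs room in the leader and so a positive control, had a median of 155 bases (70 to 324, n = 17). GCN4, the activator of amino acid synthesis, had 571 bases, with its TSS at position 140334 of chromosome V and its coding sequence at 138918 to 139763. RPC11 had 155 bases, YAP1 149 and DCD1 32. The 5 groups and this control passed a two-sided permutation test of the mean rank against all other genes, Benjamini-Hochberg adjusted over 15 groups. The adjusted p-values were 7.5e-05 for the cytosolic ribosomal proteins and the transcription factors, built on the smallest p that the permutations can give (1e-05), 1.5e-04 for the cell cycle genes, 5.6e-04 for the upstream ORF genes, 9.6e-04 for the mitochondrial ribosomal proteins and 0.00835 for ribosome biogenesis. The group's direction was shown by 99 of 132 cytosolic and 41 of 61 mitochondrial ribosomal protein genes, 42 of 59 ribosome biogenesis genes, 59 of 75 transcription factors, 24 of 27 cell cycle genes and 13 of 17 upstream ORF genes.

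Glycolysis genes had a median of 37 bases (adjusted p = 0.0696, n = 19), histone genes 32 (0.10, n = 10) and nuclear-encoded respiratory chain genes 68 (0.0535, n = 34), all short of the threshold in the permutation test. Chaperones had a median of 57.5 bases, amino acid biosynthesis 57, cell wall proteins 54, ergosterol synthesis 49, the proteasome 47 and meiosis 70, with adjusted p-values from 0.284 to 0.975. Against genes with a standard name alone the respiratory chain passed the permutation test (adjusted p = 0.0422, range over the alternatives 0.0422 to 0.382). For amino acid biosynthesis and meiosis the median lay above that of the other genes while the mean rank lay below it. Without genes whose names end in A or B after a number, a rule that removes duplicate pairs with such names only and leaves 19 cytosolic ribosomal protein genes, their median differed from that of the other genes by -18 bases with a permutation adjusted p = 0.187, within a range of 7.5e-05 to 0.187 over the alternatives. A permutation test of the median in place of the mean rank gave an adjusted p = 0.382 for both the mitochondrial ribosomal proteins and ribosome biogenesis, whose other alternatives ran from 4.5e-04 to 0.0112.

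Among the groups tested, the 3′ UTR was longest in the nuclear-encoded respiratory chain genes, with a median of 206 bases (95% bootstrap interval 178 to 244, n = 33) against 120 in all other genes. QCR9, a subunit gene of complex III, had 358 bases, COX8 206, SDH4 203 and ATP7 97. Cell wall protein genes had a median of 168 bases (141 to 200, n = 34), with SED1 at 329, CWP2 at 170, SPI1 at 166 and CIS3 at 70. Transcription factor genes had a median of 149 bases (128 to 170, n = 79), which included OAF1 at 149, YRR1 at 148 and GAT1 at 7. Histone genes had a median of 162.5 bases (150.5 to 176.5, n = 10). Each histone gene lay above the median of the other genes: HTB1 had 127 bases, HHO1 140, HTA1 159, HTZ1 160, HHT1 161, HHF1 164, HTA2 173, HHF2 176, HTB2 192 and HHT2 250.

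Shorter 3′ UTRs were found in the proteasome genes, with a median of 97 bases (79 to 126, n = 31) against 121, and in the cytosolic ribosomal protein genes, with 105 (99 to 109.1, n = 137). RPN12 had 40 bases, RPN2 97, RPN6 98 and RPN7 186. RPS31 had 48 bases, RPS14B and RPL26A 105 each, and RPS20 294. The same two-sided permutation test, adjusted over 16 groups, gave 1.6e-04 for the respiratory chain, 0.00104 for cell wall proteins, 0.00699 for transcription factors, 0.0340 for cytosolic ribosomal proteins, 0.0436 for histones and 0.0452 for the proteasome. The direction was shown by 27 of 33 respiratory chain genes, 26 of 34 cell wall genes, 53 of 79 transcription factors, 91 of 137 ribosomal protein genes and 19 of 31 proteasome genes. The other 10 groups had medians from 106 bases in amino acid biosynthesis to 150 in the cell cycle genes, with adjusted p-values from 0.120 to 0.851. In the upstream ORF genes the median lay below that of the other genes and the mean rank above it.

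The calls for cytosolic ribosomal proteins, histones and the proteasome did not hold in a permutation test of the median (adjusted p = 0.126, 0.228 and 0.254) or without the genes with names in A or B (0.403, 0.0508 and 0.0508), and their other alternatives ran from 0.0383 to 0.0526, the proteasome without UTRs that cover another coding sequence on the same strand. The differences in median from the other genes stayed about as large: without the genes with names in A or B they were -22 bases for the 19 cytosolic ribosomal protein genes left (-16 with all), 41.5 for histones (42.5) and -24 for the proteasome (-24). That rule removed no histone or proteasome gene, so there only the other genes and the adjustment changed.

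**Figure D2:**
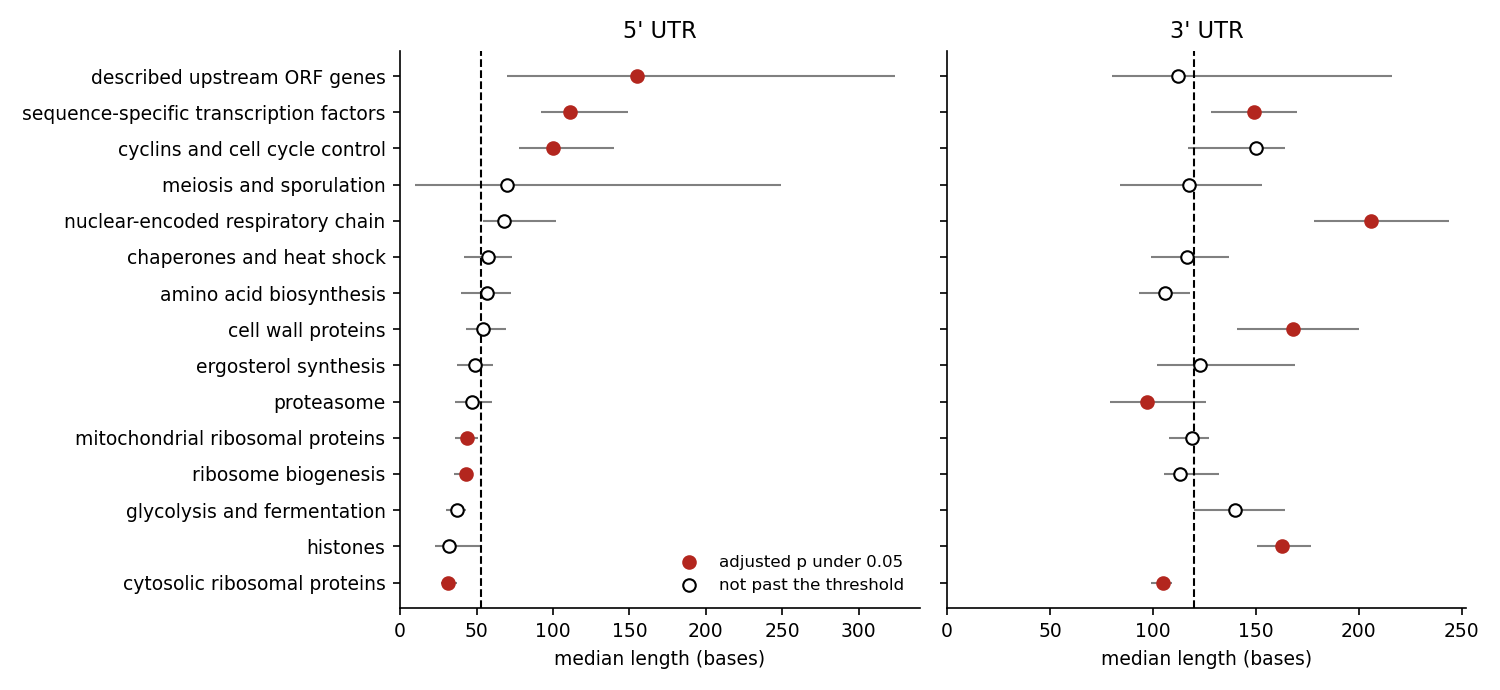
Median 5′ UTR length (left) and 3′ UTR length (right) of each gene group tested at both ends, in bases, with 95% bootstrap intervals over genes as horizontal bars; the 5′ panel's dashed line marks 53 bases and the 3′ panel's 120. Filled points are groups with an adjusted p under 0.05, such as the respiratory chain with a median 3′ UTR of 206 bases.

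Gene groups also differed in how often an end was assigned in these glucose-grown cells. Of 45 meiosis and sporulation genes, 13 had a TSS (28.9%, 95% Wilson interval 17.7 to 43.4) and 26 a PAS (57.8%, 43.3 to 71.0). SPO11, DMC1, REC8 and NDT80 had no TSS, whereas HOP1, ZIP1 and IME1 had one. The TSS of IME1 lay 4 bases inside the coding sequence, and that of MSH4, also counted, 1266 bases inside. Of 23 galactose and alternative carbon genes, 9 had a TSS (39.1%, 22.2 to 59.2) and 15 a PAS (65.2%, 44.9 to 81.2). No TSS was assigned to GAL1, GAL7, GAL10, PCK1, FBP1 or JEN1, while SUC2, HXT2, HXT4 and HXT7 had one. The TSS of SUC2 lay 50 bases inside the coding sequence, and that of MAL13, also counted, 8 bases inside. HXT6 and HXT7, and likewise MAL12 and MAL32, are near-identical copies, so which copy carries the end is uncertain. These genes were chosen as examples after their values were seen. All 137 cytosolic ribosomal protein genes, 67 mitochondrial ribosomal protein genes and 60 ribosome biogenesis genes had both ends.

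By two-sided Fisher's exact tests against all other annotated genes, adjusted over 32 tests, 15 passed. For the meiosis group the adjusted p-values were 2.67e-17 for the TSS and 2.57e-06 for the PAS, and for the alternative carbon group 1.08e-06 and 0.0117. Among the groups mapped more often, the adjusted p-values were 7.7e-08 and 3.56e-07 for cytosolic ribosomal proteins, 5.05e-04 and 0.00111 for mitochondrial ribosomal proteins, and 0.00145 and 0.00184 for ribosome biogenesis. Amino acid biosynthesis passed for both ends (0.0105 and 0.00184), the respiratory chain (0.0270) and the proteasome (0.0375) for the TSS, and cell wall proteins (0.0375) for the PAS. Against genes with a standard name alone 7 tests passed. The calls then lost in the exact tests were those for ribosome biogenesis (adjusted p = 0.0761 and 0.0929), amino acid biosynthesis (0.232 and 0.0929), the respiratory chain, the proteasome and cell wall proteins (0.374 each) and the PAS of mitochondrial ribosomal proteins (0.0761).

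Genes that differ between the mating types were too few to test. All 7 a-specific genes had both ends, and their 5′ UTRs ran from 23 bases in MFA1, a gene for the a-factor pheromone, to 108 in ASG7. STE6, the a-factor exporter, had 27 bases, the receptor gene STE2 30, BAR1 32, AGA2 54 and MFA2 62. Among the 4 alpha-specific genes, MF(ALPHA)2 had neither end. The TSS of MF(ALPHA)1 lay 8 bases inside the coding sequence with no PAS, that of STE3 lay 561 bases inside, and that of SAG1 lay 807 bases upstream of the start codon. Of the genes deleted in this strain, LEU2 and MET17 had neither end. URA3 had only a PAS, 298 bases past its stop codon in a stretch that covers another coding sequence on the same strand. HIS3, which is deleted only in part, had both ends, with UTRs of 23 and 166 bases.

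The series title names TATA elements, and the consensus TATAWAWR was searched on the sense strand upstream of each TSS. It was present 200 to 1 bases upstream in 1131 of 5204 genes (21.7%, 95% Wilson interval 20.6 to 22.9). In a control window of equal length that opens 600 bases upstream of the same TSSs it was present in 436 genes (8.38%, 7.66 to 9.16). The exact McNemar test over genes gave p = 1.51e-82, with 1029 genes holding the element only in the promoter window and 334 only in the control. The next upstream coding sequence lay a median of 367 bases from the TSS in genes with an element and 344 in genes without. The control window therefore often reached into it or beyond it. With the bases of the promoter window shuffled as the control, the element was present in 596 genes (11.5%, exact McNemar test, p = 2.37e-45). The first base of the nearest element lay a median of 80 bases upstream, with quartiles at -132 and -58. The fullest 20-base bin, -80 to -61, held 403 elements. HHF1 had its element at -69, MFA1 at -66, MFA2 at -61, SED1 at -88 and SPI1 at -83.

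The element was unevenly spread over gene groups. It was present in 8 of 10 histone genes (80%, Wilson interval 49 to 94.3), with HTZ1 and HHO1 the exceptions, and in 14 of 19 glycolysis genes (73.7%, 51.2 to 88.2). Chaperone and heat shock genes had it in 17 of 26 (65.4%), cell wall protein genes in 19 of 32 (59.4%), ergosterol synthesis genes in 12 of 24 (50%) and amino acid biosynthesis genes in 25 of 60 (41.7%). Cytosolic ribosomal protein genes had it in 12 of 137 (8.76%, 5.08 to 14.7) and ribosome biogenesis genes in 6 of 60 (10%, 4.66 to 20.1). Examples chosen after their values were seen were TDH3, PGK1 and ENO2 with an element and TPI1 and PFK1 without, and HSP26, HSP12 and HSP104 with one and SIS1 and YDJ1 without. All 8 groups passed two-sided Fisher's exact tests adjusted over 15 groups. The adjusted p-values were 1.5e-05 for glycolysis and for chaperones, 2.05e-05 for cell wall proteins, 3.13e-04 for cytosolic ribosomal proteins, 4.3e-04 for histones, 0.0011 for amino acid biosynthesis, 0.0044 for ergosterol synthesis and 0.0498 for ribosome biogenesis.

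Transcription factors (24.1%), cell cycle genes (33.3%), the respiratory chain (20.6%), the proteasome (16.1%), mitochondrial ribosomal proteins (11.9%), upstream ORF genes (27.8%) and meiosis genes (15.4%) did not pass, with adjusted p-values from 0.0873 to 1. In a window 150 to 31 bases upstream the call for ribosome biogenesis was lost (exact test, adjusted p = 0.171, range over the alternatives 0.0194 to 0.171). Genes with an element had a 5′ UTR of 50 bases at the median (46 to 52, n = 1085) against 55 (53 to 57, n = 3861) in genes without one, a difference of -5 bases (permutation test of the mean rank, adjusted p = 0.00138 over 3 measures). The 3′ UTR, 123 against 119 bases (adjusted p = 0.0801), and the distance to the next upstream gene, 367 against 344 bases (0.0903), did not pass the permutation test. With the window 150 to 31 both passed the permutation test, at adjusted p = 0.0174 (range over the alternatives 0.0174 to 0.167) and 3e-05 (3e-05 to 0.719), with differences of 6 and 97 bases.

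**Figure D3:**
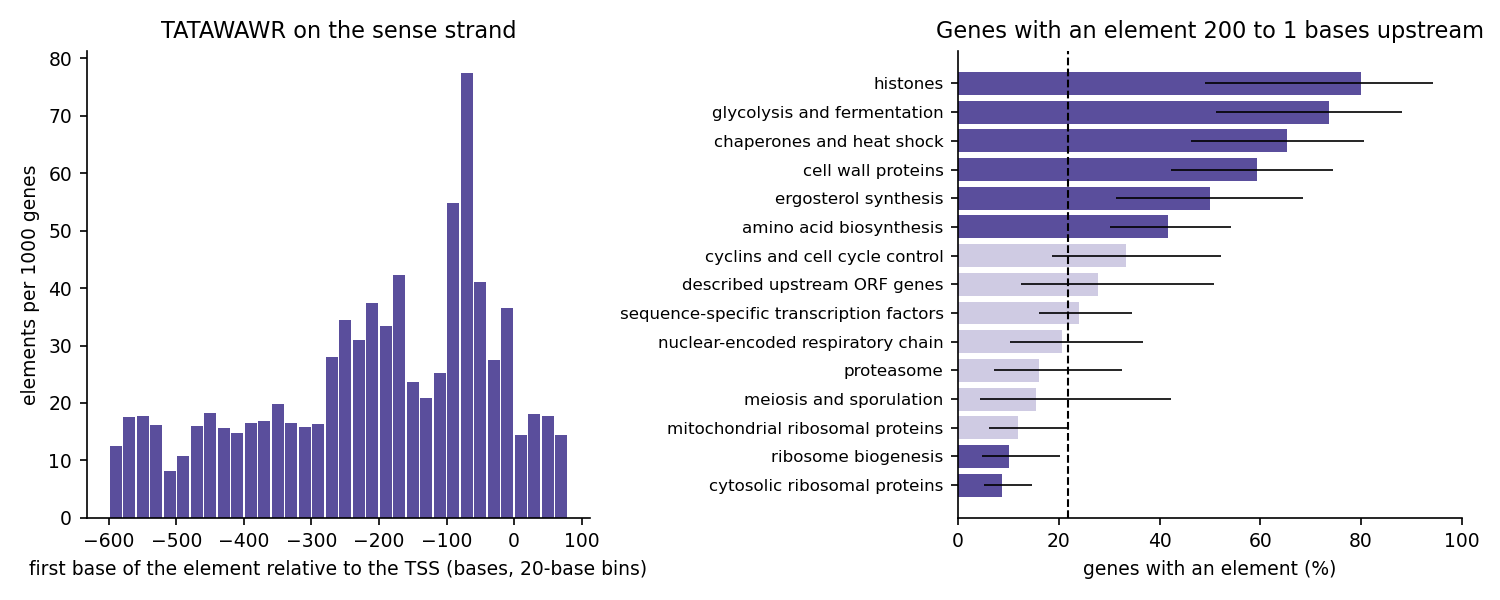
Left, TATAWAWR elements per 1000 genes in 20-base bins by the distance in bases of the first base from the TSS, with the fullest bin (403 elements) at -80 to -61. Right, percentage of genes in each group with an element 200 to 1 bases upstream, with 95% Wilson intervals, dark bars for groups with an adjusted p under 0.05 and a dashed line at 21.7%, the share in all genes.

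The bases at the TSS followed the pyrimidine-purine pattern of an initiator, with position -1 just before the TSS and +1 the TSS itself. It was present in 4899 of 5204 genes (94.1%, 95% Wilson interval 93.5 to 94.7) against 22.9% at a point 20 bases upstream in the same genes. The exact McNemar test gave a p too small to be represented as a number (-log10 p = 1003). CA stood at -1 and +1 in 2322 genes (44.6%), among them GCN4, CKS1 and HTB2. TA stood there in 1640 (31.5%), as in SFP1, HTA2 and YAP1, TG in 576 (11.1%), as in CLN3 and RPN2, and CG in 361 (6.94%), as in RPC11. MF(ALPHA)1, whose TSS lay inside the coding sequence, had TT and NOP2 had CT. Upstream of the TSS, A was most frequent at position -8, in 72.0% of genes, against a mean of 34.7% over the 100 bases on either side.

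Around the PAS, the efficiency element TAYRTA was present 80 to 25 bases upstream in 3293 of 5271 genes (62.5%, 95% Wilson interval 61.2 to 63.8) and in 9.22% (8.47 to 10.0) of windows 200 bases further downstream. The positioning element AAWAAA was present 40 to 10 bases upstream in 895 genes (17%, 16 to 18) against 7.87% (7.18 to 8.63). Both passed exact McNemar tests adjusted over the pair, at -log10 p = 640 and an adjusted p = 8.14e-47. Upstream of the PAS, efficiency elements were most frequent with their first base 45 to 41 bases before it and positioning elements 25 to 21 bases before it (569 elements). The sequence AAWAAA was as frequent from the PAS to 4 bases after it (581). With the bases of each window shuffled as the control, the efficiency element stood at 18.2%, 44.3 percentage points below the observed share. The positioning element then stood at 14.9%, 2.03 percentage points below the observed share (exact McNemar test, adjusted p = 7.89e-04, range over the alternatives 5.66e-45 to 7.89e-04). The PAS itself was T in 47.5% of genes, C in 31.2%, G in 20.8% and A in 0.512%, and the base after it was A in 88.8%.

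**Figure D4:**
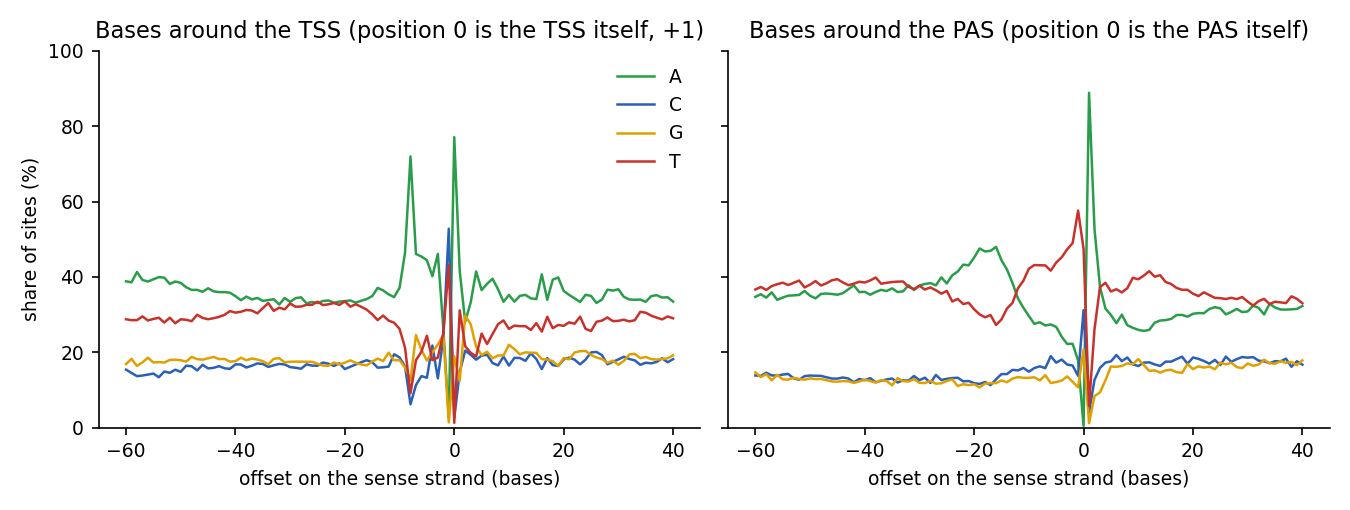
Percentage of sites with A, C, G or T at each base from 60 upstream to 40 downstream of the TSS (left) and the PAS (right) on the sense strand. A reaches 72.0% at -8 and 77.1% at the TSS, and falls to 0.512% at the PAS before rising to 88.8% at the next base.

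Upstream ATGs were present in 13 of 17 genes described as carrying upstream ORFs, a group chosen for this feature and so a positive control. GCN4 had 4, HAP4, PPR1 and PET111 had 2 each, and CLN3, YAP1, CPA1, INO2, HOL1, RPC11, FOL1 and DCD1 were among those with 1 each. SCO1, SCH9, LEU4 and TIF4631 had none between the mapped TSS and the start codon, and the TSS of CAD1 lay 28 bases inside the coding sequence. Meiosis genes had one in 6 of 11. Proteasome genes had none in 31 and ergosterol synthesis genes none in 23, while ribosome biogenesis genes had one in 2 of 59, mitochondrial ribosomal proteins in 3 of 61 and cytosolic ribosomal proteins in 11 of 132. Upstream ATGs were counted in the genomic sequence, so those inside an intron of the leader are included. RPS22B, whose genomic leader of 611 bases includes an intron, is counted with 6. FLO5 had 37 upstream ATGs, SET4 21, PDR18 19, YFL041W-A 18, RRT13 and THI72 17 each, and SAG1 and ULI1 16 each.

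An ATG was present in 953 of 4946 5′ UTRs (19.3%). Shuffling the bases within each 5′ UTR gave 59.0% on average, and the observed count was 0.327 of the shuffled one (two-sided permutation test, p = 0.0020, the smallest that 1000 shuffles can give). By two-sided Fisher's exact tests adjusted over 15 groups, the positive control (adjusted p = 7.74e-06) and meiosis genes (0.0240) were higher, and cytosolic ribosomal proteins and ribosome biogenesis (0.00351 each), the proteasome (0.00812), mitochondrial ribosomal proteins (0.00816) and ergosterol synthesis (0.0298) were lower. Glycolysis (0.0667), chaperones and the respiratory chain (0.0727 each) and 5 other groups (0.232 to 0.658) did not pass. Median 5′ UTR length was 110 bases in genes with an upstream ATG and 47 in genes without, and group shares were not adjusted for length.

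Neighbouring transcripts overlapped mainly at convergent genes. Among 1291 convergent pairs with both PASs mapped, 874 overlapped (67.7%, 95% Wilson interval 65.1 to 70.2), by a median of 91 bases. CGI121 and AMD1 on chromosome XIII overlapped by 383 bases, between positions 206156 and 206538. MNN14 and NTA1 overlapped by 331 bases, AVT5 and TEL1, the gene for a checkpoint kinase, by 327, PKH2 and SDD3 by 327, YGR153W and GTO1 by 325, and ECM10 and BUD16 by 301. YLR157W-E and YLR157C-C had the longest overlap, 391 bases. Near-identical copies of these genes were not searched for, so their positions are uncertain. In tandem pairs the upstream PAS passed the next TSS in 112 of 2060 (5.44%, 4.54 to 6.50). Fisher's exact test of the convergent against the tandem share gave -log10 p = 341. Divergent pairs had their TSSs a median of 298 bases apart (262 to 339.0, n = 1108), and 7 of these pairs overlapped (0.632%). RPS30B and FYV12 started at adjacent bases, 678849 and 678850 on chromosome XV, and CUE4 and YML100W-A lay 2 bases apart.

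**Figure D5:**
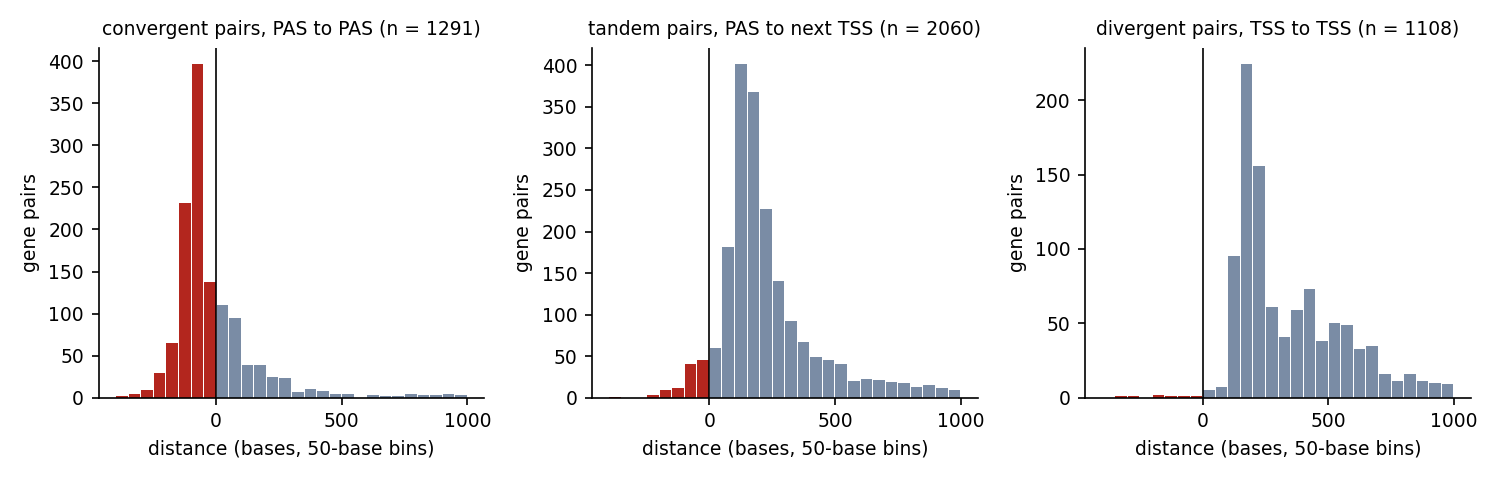
Number of gene pairs by the distance in bases between the 3′ ends of convergent pairs (left), from the PAS to the next TSS in tandem pairs (middle) and between the TSSs of divergent pairs (right), in 50-base bins. Bars below 0 are overlaps, 874 of 1291 convergent pairs, and 28, 123 and 102 pairs of 1000 bases or more are not drawn.

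Binding sites chosen by consensus were set against the gene group each is known for, and so are positive controls. The PAC site GATGAG lay within 500 bases upstream of the TSS in 59 of 60 ribosome biogenesis genes (98.3%, 95% Wilson interval 91.1 to 99.7) against 29.4% of other genes, and the RRPE site AAAWTTTT in 57 of 60 (95%) against 23.7%. Their median positions were -71.5 and -103. The proteasome regulator Rpn4 had its site upstream of 27 of 31 proteasome genes (87.1%) against 1.35%, at a median of -74. Heat shock elements lay upstream of 14 of 26 chaperone genes (53.8%) against 1.39%, at -184. Gcn4 sites lay upstream of 29 of 60 amino acid biosynthesis genes (48.3%) against 3.73%, at -158.5. Exact matches to the Rap1 pattern CACCCRNACA lay upstream of 31 of 137 cytosolic ribosomal protein genes (22.6%) against 1.60%, at -311. Rap1 sites that differ from this pattern were not counted, so the share of these genes with any Rap1 site is not given. The Puf3 site TGTANATA stood in the mapped 3′ UTR of 65 of 67 mitochondrial ribosomal protein genes (97.0%) against 13.5%. All 7 passed two-sided Fisher's exact tests adjusted over the 7 sites, with adjusted p-values from 4.12e-52 for Puf3 to 3.11e-19 for the heat shock element.

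Across the 4733 genes with both UTRs, 5′ and 3′ lengths rose together weakly. Spearman's rho was 0.129 and Pearson's r of log10 length + 1 was 0.120. Each had a two-sided permutation p = 1e-05, the smallest that 100000 permutations can give, which also stood after adjustment over the pair. This is a correlation across genes of pooled libraries, and r was 0.120 without the 2 genes farthest from the median 5′ UTR length.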

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

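The test of the flag column was chosen only after the result was seen, and the other tests in this part were chosen before their results were seen. The TSS table marks 222 sites as internal, and these drew attention because the comparisons of 5′ UTR length do not use them. A further column named flag marks 72 sites, each of them also internal. Of the matched internal sites, 209 lay past the first base of the start codon, and 204 of these lay in a coding exon at a median of 35 bases from the start codon. The genes include CAD1, a stress-response transcription factor gene, at 28 bases inside, GAT1, a regulator of nitrogen genes, at 137 and the alpha-factor pheromone gene MF(ALPHA)1 at 8.

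Ends of uncapped RNA fragments, if taken without regard to sequence, would carry no initiator. The tables argue against such ends as the source of most internal TSSs. How sites were chosen is not given, so a choice that favoured the initiator pattern cannot be excluded. Libraries with and without TAP could not be compared at these sites. The pyrimidine-purine pattern was present at 91.2% of the 204 sites, above the highest of 1000 sets of random positions in the same coding sequences (13.2% to 34.3%). A start codon annotated upstream of the one in use may account for part of the sites: the first ATG downstream of the TSS was in the annotated frame in 57% of the 200 sites that have one, above the random sets (22.3% to 42.4%). For sites within 100 bases of the start codon the margin was smaller, at 60.5% against 32.0% to 52.4% in the random sets for these sites. Which protein is made was not measured, and no biological group of samples bears on it.

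The flag column may mark internal TSSs whose first downstream ATG is out of frame. That ATG was in frame at 114 of 137 sites without the mark (83.2%) and at 0 of 63 sites with it, a difference of 83.2 percentage points (Fisher's exact test, p = 5.96e-33). The sources used here do not say what the column means.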

How the results depend on the processing

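All alternatives were fixed before the data were examined. Of the 268 values recomputed under an alternative, 204 of single groups, elements or sites and 35 main values or counts were counted as unchanged. These kept their side of the threshold and, if past it, their direction. Medians over all genes moved by less than their error, and counts of calls stayed within 1.5 times. Direction was not compared where the main value fell short of the threshold, and some of these values changed sign. An example is the TATA element in meiosis genes, with a log2 odds ratio of -0.355 on the sense strand and 0.162 on either strand. Among the single groups or measures, 19 lost the threshold and 3 reached it. The median 5′ UTR was 50 bases when TSSs inside the coding sequence entered with negative lengths, as that choice by construction adds short values. The count of groups that differ in 5′ UTR length, 6, ran from 4 with the median permuted to 7. The count of groups that differ in 3′ UTR length went from 6 to 3 when the median was permuted and to 3 without genes whose names end in A or B after a number, and the cause was not tested for either. Tests of mapped ends that passed went from 15 to 7 against genes with a standard name, and the cause was not tested. Measures that differ with a TATA element went from 1 to 3 with the window 150 to 31, and the cause was not tested. Moving the TSSs by 1 base reversed the initiator result, to -21.5 percentage points upstream and -20.5 downstream of the deposited base, since the pattern is read at another dinucleotide. The TATA enrichment stayed between 9.84 and 17.3 percentage points, the ratio of upstream ATGs between 0.308 and 0.380, the excess of convergent overlap at 53.8 or more, and rho between 0.129 and 0.131. All 7 regulatory sites passed in every window tried, and Puf3, which is read in the 3′ UTR, has no alternative. No paired analysis was possible because the tables hold no values per library, although the labels give both groups the same replicate numbers; for the same reason no replicate could be left out. Depth is unknown, so a gene without an end cannot be told from one with too few reads.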

Other observations

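The tests of trimming at templated A, of TSSs assigned downstream of an ATG and of the difference in 3′ UTR length against the overlap were chosen only after the results were seen, and the other tests of hypotheses in this part were chosen before their results were seen. Genes with and without a TATA element showed no detectable difference in the share with A at -8 or with the pyrimidine-purine pattern, the features compared. A stood at -8 in 72.6% of the 1131 genes with an element and 71.8% of the 4073 without, and the pyrimidine-purine pattern in 94.6% and 94.0% (Fisher's exact test, p = 0.627 and 0.475). Matches to TATAWAWR had a broader rise further upstream as well: 42.3 per 1000 genes began at -180 to -161, against 16.3 at -300 to -281 and 77.4 at -80 to -61. Some matches also hold the efficiency element TAYRTA. Whether those further upstream are promoter elements or 3′ end signals of upstream genes was not tested. The histone gene HTB2 has its nearest match at -180, the tRNA synthetase gene GRS2 at -175 and the kinetochore gene CEP3 at -166. Among the trinucleotides made of the same bases as ATG, ATG was the rarest in the 5′ UTR against a shuffle: the number of 5′ UTRs that hold GAT, TGA, GTA, TAG or AGT was 0.885 to 1.03 of that after shuffling.

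The hypothesis that A at -8 stands in for a missing TATA element predicts that A is rarer there in genes with an element, and its share was 0.776 percentage points higher. The hypothesis that convergent transcripts overlap since their 3′ UTRs are longer needs, as the whole cause, a difference of about 45.5 bases, what each gene of a pair would have to lose to end the median overlap of 91, and the tables argue against it. The median 3′ UTR was 122 bases in 2780 convergent genes and 119 in 2438 tandem ones, a difference of 3 bases (95% bootstrap interval 0 to 8). Whether they differ at all was not settled (permutation test of the mean rank, p = 0.210). Coding sequences of convergent pairs lay 219 bases apart at the median, 180 bases nearer than the 399 of tandem pairs (permutation p = 1e-05, the smallest that the permutations can give), a value computed without a prediction made beforehand.

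The rarity of upstream ATGs, with a ratio of 0.327 to shuffles that keep the bases of each leader, could come from TSSs assigned downstream of the ATG. TSSs assigned downstream of an ATG, as the whole cause, would leave the skipped ATGs just upstream of the TSS and raise their ratio there. In 4314 genes whose windows reach no other coding sequence, the ratio was 0.814 (0.788 to 0.851 over the shuffles) in the window directly upstream and 0.952 (0.924 to 1.00) in the next window of equal length, a difference of -0.138. Other trinucleotides of the same bases also shifted between these windows. AGT stood at 1.05 and 0.909 and TAG at 0.935 and 0.826, while GAT, GTA and TGA changed less. A shift of about this size is therefore not particular to ATG, and only the lack of a rise bears on the prediction. The direction first predicted, a rarity just upstream as in the 5′ UTR, was wrong, since skipped ATGs would lie there. Misplacement in part of the genes stays open. That start codons upstream of the coding sequence are avoided in yeast leaders is a hypothesis, on which no group of samples bears.

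A was nearly absent from the PAS itself, at 0.512%, while it stood at 17.9% to 29.7% over the 10 bases before, and the base after the PAS was A in 88.8% of genes. The absence may come from trimming, since a tail read over a templated A ends at the last base that is not A. Trimming alone would give 53.3% to 57.9% of sites followed by A, from 1000 sets of random positions within 60 bases of the PASs moved back in the same way, less than the 88.8% observed. Priming or tail calls on genomic A runs would need runs of 6 or more A in the next 10 bases, which followed 19.6% of the sites that have A as their next base. Over all sites the share was 17.7%, within the range of the 1000 random sets (15.3% to 18.2%). These shares argue against such runs as the source of most sites followed by A. Cleavage next to A remains a hypothesis, since the pattern and its tests rest on the same deposited positions.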
